A study of Rattus norvegicus with 6 samples.

How the data were processed

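Gene expression was measured in the aorta of spontaneously hypertensive rats, an inbred strain that develops high blood pressure. Per the labels, running rats had free access to a wheel for 5 weeks and were set against rats that did not run. Each of 6 Affymetrix rat genome chips carried a pool of 3 aortae, with 3 chips per group. The labels do not say how animals were divided among the pools, their sex, or the order of collection. The p-values therefore measure only the spread between pools, which may in part be technical.

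The deposited table holds intensities on a linear scale, 1 value per probe set and chip, for 8799 probe sets. The software that made these intensities is not given in the sources used here, and the deposited table has no detection calls. From the values, the mean of each array without the highest and lowest 2% of probe sets was 99.99, as a scaling of each array to a common target near 100 would give. Array medians ran from 28.5 to 32.2. On such a chip, several short probes along the last part of a transcript make up a probe set, so a value has no read depth and the number of arrays limits the precision.

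Gene symbols came from the platform annotation. A single symbol was given for 7006 probe sets, several for 308 and none for 1426, with 59 control probe sets besides. Gene identifiers of 6985 probe sets matched the gene table of the rat assembly GRCr8, used only for names, which changed 0 symbols. Only probe sets with 1 symbol were named.

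The intensities were analysed as log2(intensity + 2.4), the pseudocount being the 10th percentile of the positive values. Fold changes are on that scale and understate changes of dim genes. The highest array median was 1.13 times the lowest, over the preset limit of 10%, so the log2 values were quantile normalized. Control probe sets and the dimmest 40% of the others were left out, and 5244 probe sets covering 3173 genes were tested. Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. An exact permutation test of 3 arrays against 3 cannot go below p = 0.1, and it was used only for the control ratios.

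Gene lists for cell types of the vessel and its surroundings, vasomotor systems, metabolism and stress were fixed before the data were examined. The 28 lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01 on the brightest probe set of each gene. Mast cell markers had 3 tested genes and were not tested. Camera with an estimated correlation and fry were run as alternatives. Each list's median was also ranked among 10000 random lists of the same size and similar intensity. A list score is the mean log2 level of its genes on an array, each gene centred on its mean over the 6 arrays.

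The genes named were set by rule before the data were examined. The rule took the 12 higher and the 12 lower genes past the threshold with groups that do not overlap. As 0 passed, these places were filled by the smallest unadjusted p and are given as values. It also took up to 4 members of each described list with the smallest p, and 15 genes whatever they showed, among them Nos3, Sod1, Sod2, Sod3 and Cat. Intensities are means with SD over n = 3 arrays. No probe-level background was given, so the 95th percentile of 19 control probe sets for yeast or sense-strand targets, 40.8, served as a control level. Where all arrays of a group lay below it, a fold is given as a lower bound against that level, or left out.

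The fit was tested on simulated data with 200 changed probe sets among the 5244 of this comparison, over 20 runs. It recovered 67.5% of 2-fold, 88.7% of 3-fold and 93.9% of 4-fold changes, with 8.3 false calls per run. Each run held equal numbers of 2-, 3-, 4- and 8-fold changes, with independent noise at each probe set's own residual SD. These shares hold for that setting and do not show that changes of these sizes are absent from the real data. A list of independent genes shifted by 0.4 on the log2 scale was called in 20 of 20 runs. The alternatives were other pseudocounts, no quantile normalization, centring on medians, other filters and variance models, a block on the chip letter, other set tests, the mean of a gene's probe sets, and leaving out each array. A covariate for the 3'/5' control ratio, array quality weights and split lists were added after seeing the data. Figures were drawn with matplotlib 3.10.9.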

Results

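The data compare aortae of hypertensive rats that ran voluntarily for 5 weeks with aortae of rats that did not run, to ask how running affects gene expression in the vessel. Each group had 3 arrays, called A, B and C, and each array a pool of 3 aortae. Smooth muscle and matrix transcripts were among the bright signals. Acta2, smooth muscle actin, measured 4052 ± 987 in non-runners and 4080 ± 288 in runners (intensity, SD, n = 3). Eln, elastin, measured 3608 ± 404 and 3461 ± 276. Ucp1, the uncoupling protein of brown fat, was also bright and measured 1251 ± 431 and 1200 ± 324.

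Non-runner B stood apart from the other arrays. The 3'/5' intensity ratio of beta-actin, which grows as signal from the 5' end is lost, was 2.14 there and 1.22 to 1.67 elsewhere. For GAPDH it was 1.95 there and 1.11 to 1.39 elsewhere. The beta-actin ratio averaged 1.70 ± 0.43 in non-runners and 1.31 ± 0.11 in runners (SD, n = 3, two-sided exact permutation p = 0.3). For GAPDH the means were 1.52 ± 0.38 and 1.17 ± 0.06 (exact permutation p = 0.1, the smallest that 3 against 3 allows). The SD of log2 differences between arrays was 0.56 to 0.61 in pairs with non-runner B and 0.36 to 0.41 in the others.

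**Figure D1:**
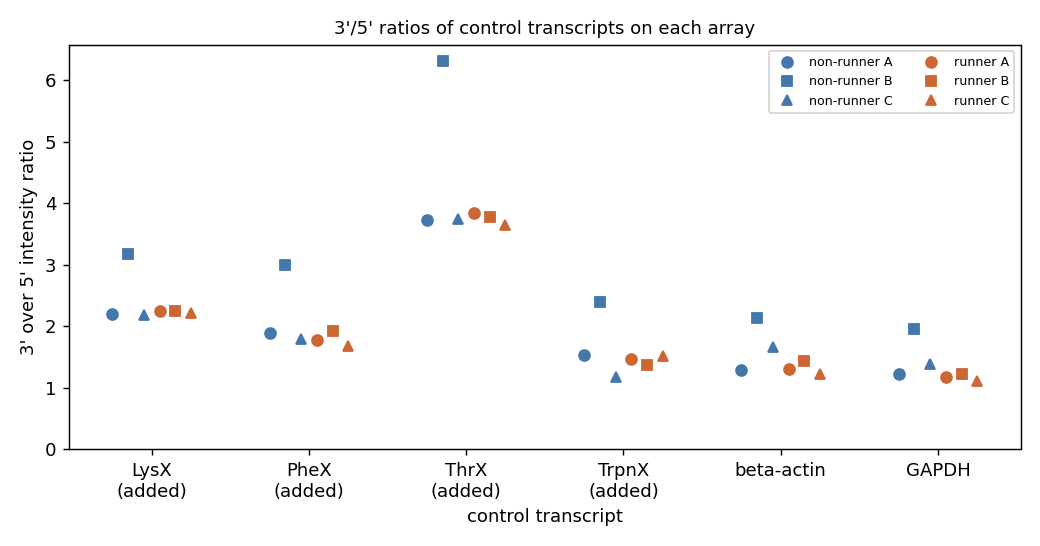
The 3'/5' intensity ratio (vertical axis, no unit) of 4 added bacterial transcripts, beta-actin and GAPDH (horizontal axis), with a point per array. Non-runner B is highest for each transcript, with 2.14 for beta-actin and 1.95 for GAPDH.

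Chaperone genes were lower as a group in the aortae of runners, and lipid synthesis genes were higher as a group, by limma's camera at a preset correlation. Neither call held with an estimated correlation (adjusted p = 0.479 for both lists). Heat shock proteins and chaperones, which help proteins fold, had a median log2 difference of -0.43 over 20 genes. Cholesterol and lipid synthesis genes had a median of 0.40 over 18 genes. Nerve and Schwann cell markers (median -0.30), glycolysis genes (0.22) and red blood cell and platelet markers (0.35) also passed camera at the preset correlation. Each of these calls was also lost with an estimated correlation (adjusted p = 0.525 for each), and fry called 0 lists. No single probe set passed: 0 were higher and 0 lower of 5244 by limma at an adjusted p under 0.05, and the smallest adjusted p was 0.2. At an unadjusted p under 0.05, 203 were higher and 221 lower, 424 in all where 262 are expected with no effect. Values of the groups did not overlap for 786 probe sets, 15% against the 10% that chance gives.

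**Figure D2:**
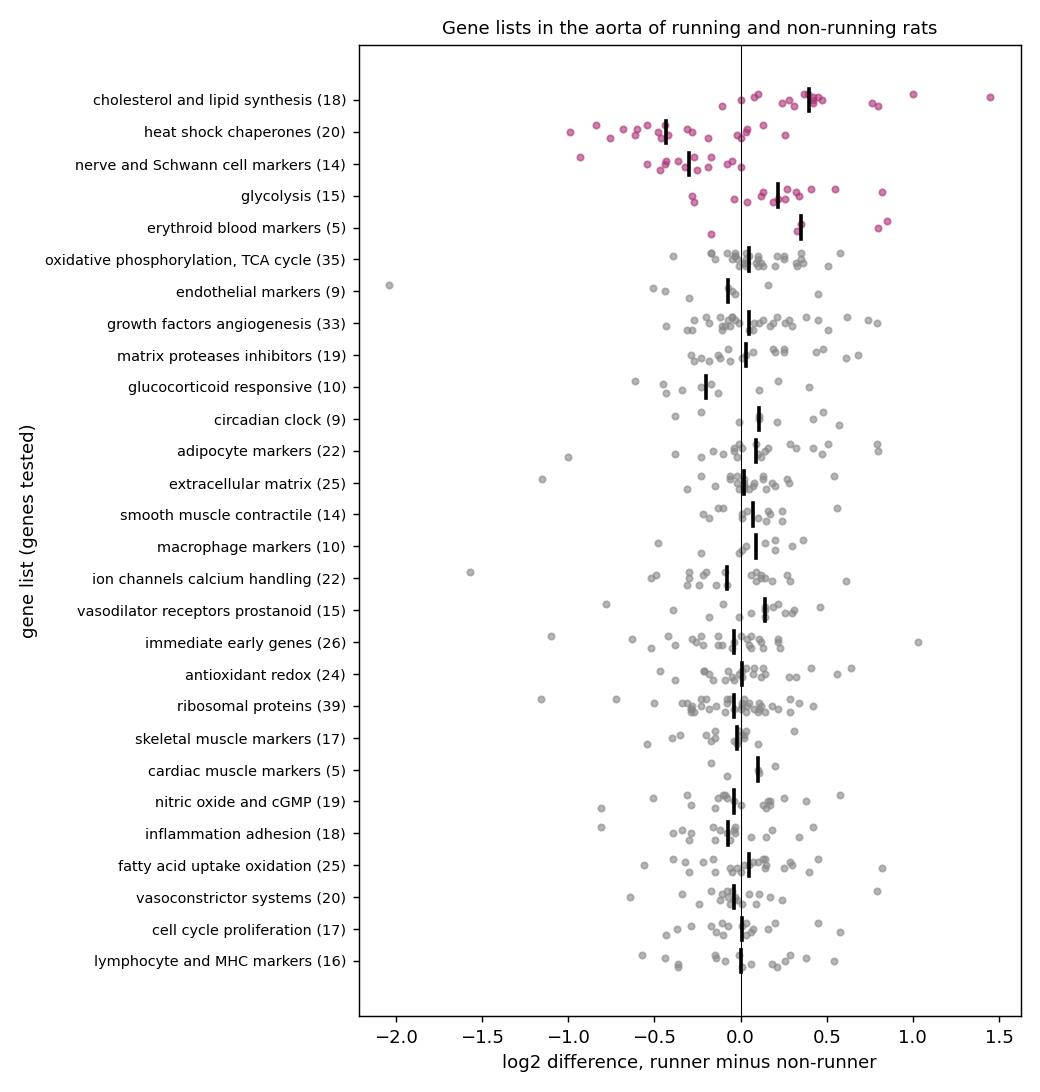
Log2 difference, runner minus non-runner (horizontal axis), of each tested gene in 28 lists (vertical axis), with a point per gene and a black bar at the list median. Coloured points mark the 5 lists past the camera test at its preset correlation, 0 of which pass with an estimated one, among them chaperones at -0.43 and lipid synthesis at 0.40.

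Of the 20 heat shock and chaperone genes, 15 were lower in runners. Hsph1, a chaperone of the Hsp110 family, measured 924 ± 197 in non-runners and 502 ± 25.7 in runners (log2 difference -0.84 ± 0.18 SE). Dnajb1, an Hsp40 co-chaperone of Hsp70, measured 662 ± 163 and 325 ± 81.5 (-0.99 ± 0.25 SE). Dnaja1, another Hsp40 protein, differed by -0.68 ± 0.15 (SE) and Canx, the endoplasmic reticulum chaperone calnexin, by -0.61 ± 0.15. For 10 members, all lower, limma's p passed 0.05 when adjusted over the list alone, and for 0 when adjusted over all probe sets. Beside those 4 they were Cryab, Hspb1, Hspa1a, Hspd1, Calr and Hsp90ab1, named after their values were seen. Hsp90b1, at 551 ± 121 and 542 ± 85.1, and P4hb, at 1091 ± 172 and 1047 ± 19.1, were the members nearest to 0, and were also singled out afterwards. The list score was -0.20 to -0.16 on the runner arrays and 0.07 to 0.25 on the non-runner arrays, highest on non-runner B. Camera gave an adjusted p = 1.17e-06 at the preset correlation, adjusted p = 0.479 with an estimated correlation, and fry an adjusted p = 0.0725. The median was -0.34 without non-runner B, and -0.27 with the mean of each gene's probe sets in place of the brightest.

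Of the 18 cholesterol and lipid synthesis genes, 16 were higher in runners. Me1, malic enzyme, which supplies NADPH for fatty acid synthesis, measured 451 ± 64.4 in non-runners and 881 ± 16.5 in runners, a 2-fold difference. It was the 1 member to pass adjusted over the list alone (limma adjusted p = 0.00349), and 0 passed over all probe sets. Acly, which makes cytosolic acetyl-CoA from citrate, differed by 0.45 ± 0.14 (log2, SE) in the brightest of its probe sets and by 1.32 ± 0.27 in another. Scd, a stearoyl-CoA desaturase, differed by 0.42 ± 0.15 and 1.67 ± 0.35 in its probe sets, and Scd2 by 0.47 ± 0.16. Fasn, fatty acid synthase, measured 1249 ± 511 and 1958 ± 148. The list score was 0.07 to 0.32 on the runner arrays, -0.08 and -0.01 on non-runners A and C, and -0.56 on non-runner B. Camera gave an adjusted p = 7.58e-07, adjusted p = 0.479 with an estimated correlation, and fry an adjusted p = 0.303. Without non-runner B the median was 0.32 and the adjusted p from limma's camera 0.000218.

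**Figure D3:**
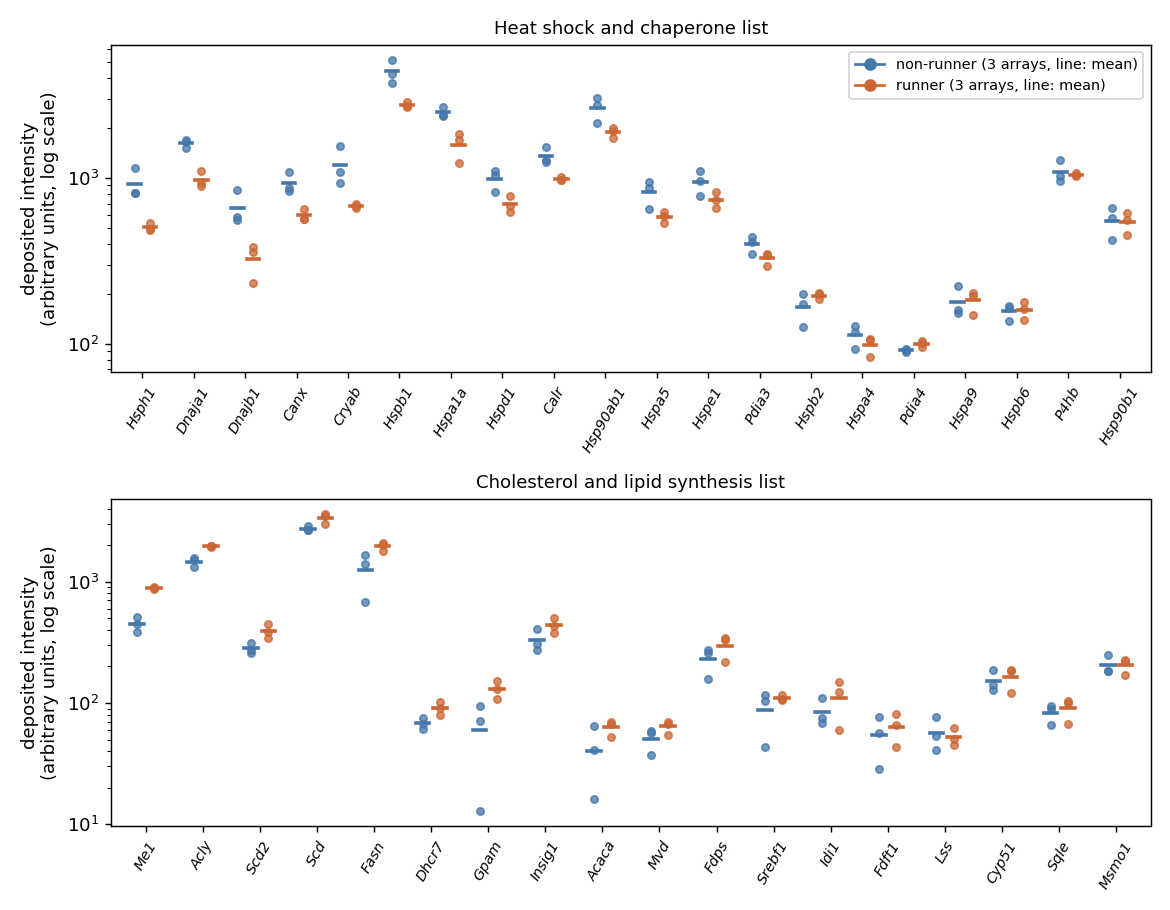
Deposited intensity (log axis, arbitrary units) of each tested chaperone gene (upper panel) and lipid synthesis gene (lower panel), ordered by p, with a point per array and a line at the group mean. Hsph1 lies at 924 in non-runners and 502 in runners, and Me1 at 451 and 881.

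Adipocyte markers, which share some genes with the lipid synthesis list, had a median of 0.09 over 22 genes (limma camera adjusted p = 0.29). Fabp4, a fatty acid binding protein of fat cells, measured 485 ± 71.0 in non-runners and 676 ± 68.0 in runners. Lpl, lipoprotein lipase, measured 819 ± 61.3 and 625 ± 40.9. Cfd, adipsin, measured 483 ± 135 and 498 ± 35, and Cd36, a fatty acid transporter, 56.0 ± 27.9 and 63.6 ± 5.9. The adipocyte score was -0.54 on non-runner B and 0.01 to 0.21 on the other arrays, and the list median was -0.12 without non-runner B.

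All 14 nerve and Schwann cell markers had a difference at or below 0. Th, tyrosine hydroxylase of sympathetic nerves, measured 82.5 ± 16.6 in non-runners and 45.1 ± 20.8 in runners. S100b, a Schwann cell protein, measured 242 ± 41.8 and 169 ± 41.5, and Pmp22, a myelin protein, 1010 ± 142 and 790 ± 22.2. Snap25, of synaptic vesicle fusion, was at least 1.04-fold higher in non-runners, but only non-runner A (49.6) lay above the control level. Of the 14, 0 passed limma's test over all probe sets and 0 adjusted over the list alone. Camera gave an adjusted p = 0.00535, adjusted p = 0.525 with an estimated correlation, and fry an adjusted p = 0.402. The groups overlapped, with scores of 0.05 to 0.29 in non-runners and -0.44, 0.17 and -0.21 in runners A, B and C. The call was lost without runner A (median -0.19, limma camera adjusted p = 0.178), without non-runner A (-0.25, 0.0752) and with the dimmest 60% left out (-0.25, 0.0584), and the median was -0.57 without runner B.

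Of 15 glycolysis genes, 12 were higher in runners. Aldoa, an aldolase, measured 510 ± 214 in non-runners and 828 ± 72.7 in runners. Hk2, a hexokinase of muscle and fat, measured 147 ± 7.7 and 197 ± 27.0, and Pkm, pyruvate kinase, 1029 ± 151 and 1268 ± 69.2. Pgam1 measured 1206 ± 130 and 1413 ± 22.9. Camera gave an adjusted p = 0.0158, adjusted p = 0.525 with an estimated correlation, and fry an adjusted p = 0.346, and 0 members passed adjusted over the list alone. The score was lowest on non-runner B (-0.22). The call was lost without that array (median 0.15, limma camera adjusted p = 0.179), without runner A (0.12, 0.14), with the beta-actin ratio as covariate (0.13, 0.171) and with array quality weights (0.16, 0.0688).

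Red blood cell and platelet markers were represented by 5 genes, of which 4 were higher in runners. Hbb, a beta-globin, measured 1053 ± 226 in non-runners and 1943 ± 838 in runners, with 2911 on runner C. Hbb-b1, another beta-globin, measured 419 ± 54.0 and 793 ± 425, with 1284 on runner C. Like Hbb it was highest on that array, so it may not be a separate measure. Pf4, a platelet chemokine, measured 140 ± 8.2 and 179 ± 8.6. Alas2, of haem synthesis in red cells, measured 119 ± 4.1 and 155 ± 49.7. Camera gave an adjusted p = 0.0215, adjusted p = 0.525 with an estimated correlation, and fry an adjusted p = 0.346, and 0 members passed adjusted over the list alone. The score was 0.61 on runner C. The call was lost without non-runner A (median 0.37, limma camera adjusted p = 0.0752), B (0.38, 0.0532) or C (0.31, 0.0949). It was also lost without runner C (0.33, 0.0592) and with the beta-actin ratio as covariate (0.35, 0.116), and the median was 0.55 without runner A.

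Lists for the vessel wall itself did not pass. Smooth muscle contractile genes had a median of 0.07 (limma camera adjusted p = 0.347), with Myh11, smooth muscle myosin, at 1939 ± 32.5 in non-runners and 1737 ± 170 in runners. Itga8, an integrin of smooth muscle, measured 275 ± 50 and 405 ± 7.9. Endothelial markers had a median of -0.07 and a mean of -0.32, with 7 of 9 lower (adjusted p = 0.271, and 0.0611 without non-runner B). Their score was -0.24 to -0.08 on the runner arrays and 0.04 to 0.26 on the non-runner arrays. Egfl7, secreted by endothelial cells, measured 119 ± 28.3 in non-runners and 28.6 ± 12.3 in runners, at least 2.73-fold lower, and passed adjusted over the list alone (limma adjusted p = 0.00483). It had by far the largest difference of the 9 and weighs most in their mean and score. Among the 7 lower, Icam2, Thbd and Edn1 lay near 0. Flt1, a VEGF receptor, measured 63.6 ± 3.4 and 47 ± 9.4, while Pecam1, another endothelial marker, measured 134 ± 58.3 and 171 ± 12. Extracellular matrix genes had a median of 0.02 (adjusted p = 0.347), and matrix proteases and their inhibitors 0.03 (0.271).

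Genes that set vessel tone did not pass as groups either. Nos3, the endothelial nitric oxide synthase, measured 87.9 ± 17.3 in non-runners and 62.1 ± 10.6 in runners (log2 difference -0.51 ± 0.21 SE, limma adjusted p = 0.597). The nitric oxide and cGMP list had a median of -0.04 while its test leaned upward (adjusted p = 0.78). Edn1, endothelin, lay below the control level in both groups, at 23.9 ± 7.1 and 23.9 ± 5.4. Agtr1a, an angiotensin receptor, measured 77.9 ± 17.3 and 65.9 ± 14.4, and the vasoconstrictor list had a median of -0.04 (adjusted p = 0.876). Ptgir, the prostacyclin receptor, measured 233 ± 3.8 and 139 ± 40.1, and the vasodilator list had a median of 0.14 (adjusted p = 0.439). Ion channels and calcium handling genes had a median of -0.08 (adjusted p = 0.393). Kcna5, a voltage-gated potassium channel of that list, measured 35.2 ± 14.5 in non-runners and 10.2 ± 0.5 in runners, both means below the control level and only non-runner A above it (limma adjusted p = 0.00388 over the list alone and 0.214 over all probe sets).

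Antioxidant genes had a median of 0.01 (limma camera adjusted p = 0.583). Sod2, the mitochondrial superoxide dismutase, measured 74.2 ± 18.1 in non-runners and 116 ± 7.6 in runners (log2 difference 0.64 ± 0.20 SE, limma adjusted p = 0.521). Sod1, the cytosolic form, measured 992 ± 105 and 957 ± 87.0. Sod3, the extracellular form, measured 1362 ± 501 and 1693 ± 108, and Cat, catalase, 173 ± 10 and 174 ± 11.7. Oxidative phosphorylation and citric acid cycle genes had a median of 0.05 (adjusted p = 0.114), and fatty acid uptake and oxidation genes 0.05 (0.799). Without non-runner B the median turned to -0.13 for fatty acid uptake and oxidation (limma camera adjusted p = 0.061), -0.09 for antioxidant genes, -0.03 for smooth muscle genes and 0.02 for ion channels. It kept its sign but moved to 0.04 for the vasodilator list, 0.09 for extracellular matrix (adjusted p = 0.061), 0.07 for proteases and inhibitors, -0.07 for the vasoconstrictor list and 0.01 for oxidative phosphorylation.

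Of the 12 higher genes with the smallest p, 0 passed limma's test. Pnpla3, a lipid droplet protein, measured 78.1 ± 23.7 in non-runners and 194 ± 20 in runners, and Pc, pyruvate carboxylase, 116 ± 48.7 and 269 ± 31.9. Pygb, glycogen phosphorylase, measured 14.8 ± 7.6 and 39.7 ± 4.8, both means below the control level. P2ry6, a nucleotide receptor, measured 39.2 ± 6.7 and 67.2 ± 5.1, with the non-runner mean below the control level. Jun, a transcription factor, measured 79.7 ± 11.7 and 143 ± 8.5 in the probe set with the smallest p, but its 4 probe sets disagreed, with log2 differences of 0.84, 0.22, -0.05 and -0.47. Ddr1, a collagen receptor, was at least 1.46-fold higher in a dim probe set, while its brighter probe sets differed by -0.15 and -0.12. With non-runners below the control level, Pdlim2 was at least 1.39-fold, Dnase1 at least 1.08-fold and Ireb2 at least 1.02-fold higher in runners. These bounds come from mean values and carry no error. Ireb2 lay above the control level only on runner B (50.1), and Dnase1 lay below it on runner A (40.3). Adjusted p for the 12, which include Me1, Acly and Scd, lay between 0.214 and 0.31.

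Among the 12 lower genes with the smallest p, which include Hsph1, Dnaja1, Egfl7 and Kcna5, adjusted p from limma lay between 0.214 and 0.319. Myc, a growth-linked transcription factor, measured 82.1 ± 25.7 in non-runners and 36.6 ± 6.4 in runners, and Gnl3, a nucleolar protein of growing cells, 66.1 ± 2.5 and 37.1 ± 6.3. Tango2 measured 110 ± 13.0 and 57.5 ± 5.6, Rasl11b 164 ± 22.9 and 90.7 ± 12.6, and Inpp4a, an inositol phosphatase, 104 ± 14.1 and 64.4 ± 1.4. Syt5, Apol3l1 and Faim2 had means below the control level in both groups. The runner means of Myc and Gnl3 were also below it. For some named genes the tested probe sets differed in sign, and the direction given held in 3 of 5 for Canx, 4 of 5 for Nos3, 2 of 3 for Gnl3 and Agtr1a, 1 of 3 for Sod1 and Myh11, and 1 of 2 for Tango2. In these genes 0 probe sets of the opposite sign had an unadjusted p under 0.05.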

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

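The rule that picked this result was chosen after the data were seen. Among the 59 control probe sets, which were left out of the limma comparison, the middle probe set of the rat hexokinase control was brighter on each runner array than on any non-runner array. Its intensity averaged 36.0 ± 4.1 in runners and 12.1 ± 1.2 in non-runners (SD, n = 3). Both means lie below the control level of 40.8, so no fold is given and neither is established as signal. The probe set for the 3' end of that control measured 40.4 ± 3 in runners and 31.4 ± 14.1 in non-runners, and the one for the 5' end 13.6 ± 1.7 and 7.6 ± 5.1.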

How the results depend on the processing

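The beta-actin 3'/5' ratio as a covariate, array quality weights and the split lists were chosen after the data were seen; the other alternatives were planned. The counts of 0 probe sets higher and 0 lower by limma held in every alternative that kept all 6 arrays, with 298 to 617 probe sets at an unadjusted p under 0.05. Leaving out each array in turn gave 0 to 4 higher and 0 to 1 lower. Without non-runner A, Pdlim2 was higher (limma adjusted p = 0.0467) and Plpp2 lower. Pdlim2 lay below the control level on the non-runner arrays left, at 12.7 and 15.3, so no difference is given. Without non-runner C, 4 were higher, Rbfox2, Erbb2 and 2 without a gene symbol. Plpp2, Rbfox2 and Erbb2 are named after their values were seen. Scaling moved the median of all genes by at most 0.04 in size. On each array 27.3% to 29.7% of probe sets lay under an intensity of 10, where signal is below the control level of 40.8. The array medians, 28.5 to 32.2, also lay below that level, so most probe sets on each array did. Some of these were among the probe sets tested, such as that of Edn1.

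All 100 results for the 5 called lists kept their direction, and 78 stayed past the threshold. The direction could not change under the other variance models, the block or the other set tests, which leave the log2 differences unchanged. With an estimated correlation 0 lists were called and with fry 0, at unchanged medians of 0.40 (lipid synthesis), -0.43 (chaperones), -0.30 (nerve), 0.22 (glycolysis) and 0.35 (blood). The other alternatives that kept 6 arrays called 4 to 7, and leaving out each array called 3 to 6, with 3 without non-runner A, non-runner B or runner A. The nerve list was not called with the dimmest 60% left out (-0.25), and ranged from -0.57 to -0.19 as arrays were left out. Glycolysis was not called with the covariate (0.13) or weights (0.16), and ranged from 0.12 to 0.26. The blood list was not called with the covariate (0.35), and ranged from 0.31 to 0.55. The cause was not tested, except that leaving out arrays leaves fewer samples.

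Of 2299 results for named genes, 2260 kept their sign and side of the threshold, 37 changed sign, 1, Cat without quantile normalization, rounded to 0, and 1, Pdlim2, passed the threshold. Among the 24 genes chosen by p, 0 changed sign. Leaving out arrays could not change it, since these genes were chosen with groups that do not overlap. For any gene, the other variance models and the block leave the log2 difference unchanged. The sign changes were all of genes that did not pass, and the cause was not tested. Without quantile normalization they were Eln (-0.06) and Edn1, whose differences are left out as it lay below the control level in both groups. With arrays centred on medians they were Cat (-0.04), Acta2 (-0.01) and Eln (-0.11). With the covariate they were Sod3 (-0.11), Cd36 (-0.20), Cfd (-0.06), Acta2 (-0.18), Casq2 (-0.11), Pecam1 (-0.07), Hsd11b1 (0.07), Vcam1 (-0.02), Gucy1b1 (0.02), Adm (0) and Ptger3 (-0.05). With array weights they were Cat (-0.01), Cd36 (-0.08), Cfd (-0.12) and Edn1 (0.03). As arrays were left out, Sod1 ranged from -0.10 to 0.09, Cat from -0.04 to 0.05, Cd36 from -0.18 to 0.59, Ucp1 from -0.33 to 0.18, Cfd from -0.09 to 0.28, Acta2 from -0.06 to 0.32, Eln from 0 to 0.13, Edn1 from -0.19 to 0.15, Casq2 from -0.02 to 0.31 and Myl2 from -0.07 to 0.22.

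The labels give chip letters A, B and C in both groups, with a further letter, D, E or F, on each runner chip, and do not say that a letter pairs chips. Arrays of the same letter did not deviate together (correlations -0.09, -0.04 and -0.05), and 0 arrays correlated best with their own letter. With the letter as a replicate block, 0 probe sets were higher, 0 lower and 5 lists called, and 359 probe sets had an unadjusted p under 0.05.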

Other observations

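The tests of technical explanations given here were chosen after the results were seen, and for the test that leaves out non-runner B the value itself was already known. The lists were split after their values were seen. The counts over splits of the arrays were planned.

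Lists for immune cells, growth and surrounding tissue did not pass limma's camera test. Macrophage markers had a median log2 difference of 0.09 (adjusted p = 0.37), with Lgals3, galectin-3, at 206 ± 9 in non-runners and 268 ± 25.9 in runners (SD, n = 3). Lymphocyte and MHC genes had a median of 0 (adjusted p = 0.949), with Cd74, the invariant chain of MHC class II, at 430 ± 90.6 and 290 ± 52.2. Inflammation and adhesion genes had a median of -0.07 (adjusted p = 0.799), and Ccl2, a monocyte chemokine, measured 64.9 ± 22.8 and 84.8 ± 3.4. Growth factor and angiogenesis genes had a median of 0.05 (adjusted p = 0.271), with Pdgfra, a PDGF receptor, at 320 ± 75.8 and 235 ± 11.5 and Pdgfrb, another PDGF receptor, at 51.2 ± 21.1 and 87.7 ± 21.8. Cell cycle genes had a median of 0.01 (adjusted p = 0.949), ribosomal protein genes -0.04 (0.624), skeletal muscle markers -0.02 (0.776) and cardiac muscle markers 0.10 (0.78). Without non-runner B the median turned to -0.07 for growth factors, -0.08 for cell cycle genes and -0.02 for cardiac markers, and moved to -0.20 for skeletal muscle and -0.12 for inflammation. Probe sets differed in sign for Cd74 (3 of 4 lower) and Pdgfra (1 of 2 lower).

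Genes that follow handling, hormones or time of day did not pass as lists either. Immediate early genes had a median of -0.04 (limma camera adjusted p = 0.475) with members on both sides. At limma's unadjusted p under 0.05, 3 were lower and 1 higher. Myc, lower in runners with a mean there below the control level, passed adjusted over the list alone (limma adjusted p = 0.0384). Klf4 measured 416 ± 81.2 in non-runners and 272 ± 39.1 in runners (SD, n = 3), and Jund 121 ± 61.5 and 229 ± 42. Glucocorticoid-responsive genes had a median of -0.20 (adjusted p = 0.271), with Cebpd at 126 ± 24.9 and 81.8 ± 12.3 in the brightest of its probe sets, of which 2 of 3 were lower. Circadian clock genes had a median of 0.11 (adjusted p = 0.271), with Dbp, a clock output gene, at 43.1 ± 11.9 and 57.8 ± 7.3, Bhlhe40 at 40 ± 7.7 and 57.4 ± 0.6, and Per2 at 48.9 ± 1.6 and 38 ± 5.5. The Bhlhe40 mean in non-runners and the Per2 mean in runners lay below the control level. The clock median was 0.22 without non-runner B.

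Within the lipid synthesis list, the 7 fatty acid and glyceride genes, such as Me1, Fasn and Gpam, had a median log2 difference of 0.76. Their score was higher in runners by 0.76 (SE 0.25), and by 0.53 (SE 0.11) without non-runner B. With an estimated correlation, limma's camera gave this part, split off after its values were seen, an unadjusted p = 0.0136, against an unadjusted p = 0.0342 and adjusted p = 0.479 for the whole list. The 9 sterol genes, such as Sqle and Cyp51, had a median of 0.24, but their score difference of 0.19 (SE 0.21), or 0.08 (SE 0.23) without non-runner B, was within its error. The sterol score was -0.24 on runner C, below non-runners A (0.10) and C (-0.07), and limma's camera with an estimated correlation gave an unadjusted p = 0.3 for this part.

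The score of the whole lipid synthesis list was higher in runners by 0.44 (SE 0.19). If more adipocytes in the runner pools raised the list and the adipocyte markers outside it alike, the gap between their scores would not change. The list score exceeded that of the markers by 0.39 (SE 0.11) more in runners. The groups did not overlap, but the nearest arrays were non-runner B (-0.04) and runner C (0.09). Those markers did not move alike, with 11 of 20 higher in runners, and the arrays are few. More adipocytes therefore cannot be set aside. Non-runner B carried part of the difference in list score, which was 0.27 (SE 0.10) without that array. Weak 5' signal on it alone would leave none, but an SE from so few arrays is too uncertain to set that explanation aside. Weak 5' signal across the non-runner arrays cannot be told apart from running, since with the beta-actin ratio as covariate the score difference was within 2 SE of 0, at 0.27 (SE 0.21) for the list and 0.54 (SE 0.28) for the fatty acid part, although limma's camera at the preset correlation still called the list (median 0.32, adjusted p = 0.00455), a call that without the covariate is lost at an estimated correlation (adjusted p = 0.479). A response of lipid synthesis to running may be a further explanation, and it was not tested.

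The chaperone list was lower in runners, with its median below 0 in 13 cytosolic and mitochondrial chaperones (-0.48) and 7 of the endoplasmic reticulum (-0.28, with 2 of 7 higher), whose unadjusted p from limma's camera with an estimated correlation was 0.0225 and 0.14, against an unadjusted p = 0.0315 and adjusted p = 0.479 for the whole list. With the beta-actin ratio as covariate the difference in chaperone score was -0.29 (SE 0.04), so weak 5' signal as that ratio measures it did not remove the difference. The GAPDH ratio was not used as a covariate, and an SE from so few arrays is too uncertain to set weak 5' signal aside. A shift shared by genes of similar level does not account for the lower chaperone list, since 0% of 10000 random lists had a lower median. Gentler or quicker collection of the runner aortae cannot be told apart from running, since immediate early genes went both ways. At limma's unadjusted p under 0.05, 3 of them were lower and 1 higher. Their median of -0.04 turned to 0.04 without non-runner B. A lower chaperone level in the vessel wall of runners may be a further explanation, and it was not tested.

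Non-runner B had weak 5' signal in tissue transcripts and in 4 bacterial transcripts added as controls. Tissue RNA broken down before those were added would leave them alike on all arrays. Instead, all 4 had their highest 3'/5' ratio on non-runner B, with a median excess over the other arrays of 0.74 on the log2 scale. Its SE, 0.06, is over the 4 transcripts on that array and does not measure the spread between arrays. This excess was 1.12 times that of beta-actin and GAPDH, consistent with a labelling reaction that copied less of the 5' ends on that array. When the controls were added is not given in the sources used here, breakdown after that point was not tested, and no biological explanation was tested.

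The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 0 probe sets past limma's adjusted threshold and the highest other split 0, so 10 of 10 gave as many. At an unadjusted p under 0.05 the real split gave 424 and the highest other 283, so 1 of 10 gave as many. For gene lists the real split called 5 and the highest other 7, and 4 of 10 called as many. The lipid synthesis list had an adjusted p = 7.58e-07 in the real split and 1.35e-06 as the smallest of the others, and was called in 3 of them. The chaperone list had 1.17e-06 and 0.0197 and was called in 2 others, and the blood list had 0.0215 and 0.0512. The nerve list (0.00535) and glycolysis (0.0158) had smaller values in other splits, down to 7.46e-07 and 0.00396.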
